A study of Caenorhabditis elegans with 2 samples.

How the data were processed

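The samples were 2 biological replicates of a TF ChIP-seq experiment on L1 larvae carrying EGFP-tagged LIN-13, in 1 group, per the labels. The antibody label names the target itself. The deposited files were peak lists, not reads. According to the deposited descriptions of the files, a list was called on each replicate's alignment against a control alignment, another list was called on the alignments of both replicates pooled, and each kept peaks and background, which gives 30000 calls. A further list, the optimal set by irreproducible discovery rate (IDR), was derived from the pooled list and both replicates' lists. Every list was deposited in the ce10 and the ce11 build. The aligner, the peak caller, their versions, the IDR threshold and the read depth are not given in the sources used here. Control samples were not analysed here, and the lists cannot show what an untagged strain would give.

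Values per call were the authors' own. The deposited signal of a call is the score the peak caller gave it against the control, on a scale that the sources used here do not state and that differs between lists, so signals were ranked and compared only within a list, and set side by side between replicates only to describe a peak. The −log10 q-value in the deposited lists was used only to count calls with a q-value under 0.05. It reaches a ceiling shared by many calls, 3.61 for 2026 calls in the pooled list, and so could not rank the strongest ones. Most pooled calls were 324 bp wide and 128 were narrower, down to 81 bp. These narrow calls are strong peaks, since 82 of the 100 strongest reproducible peaks were narrow.

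The ce11 IDR set was the main peak set, and its summits were the positions analysed. It was identical to the 2333 pooled calls of highest signal. Protein-coding genes and transcript 5' ends came from Ensembl release 115 on WBcel235, the assembly of ce11, for 19973 genes and 29314 distinct 5' ends on the 6 nuclear chromosomes. Many C. elegans transcripts are trans-spliced, so that an annotated 5' end can lie downstream of the site where transcription starts. A gene counted as having a peak when a summit lay within 500 bp of one of its 5' ends, and a summit could count for several genes. Distal means farther than 1000 bp from any 5' end. Sequence came from the RefSeq copy of the same assembly, in windows of 201 bp centred on the summit.

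Calls of the replicates were matched to peaks by the nearest summit within 100 bp. Placement near 5' ends was tested with 1000 random placements within the same chromosome (one-sided, smallest p 0.001), and exons, introns and sequence between genes were compared with 200 placements, without a test. Densities were compared with exact binomial tests against the share of bases or of 5' ends. Gene lists were tested with two-sided Fisher exact tests against all other protein-coding genes, adjusted over 26 lists by the Benjamini-Hochberg method, at a threshold of 0.05. Peak strength was compared by the difference of median signal ranks with 100000 resamples for lists with at least 10 genes with a peak (two-sided, smallest p 1e-05). Words were compared between each summit and a position 1000 bp away on a random side by exact McNemar tests, adjusted over 9 motifs or 2080 6-mers. E2F-like sites were the words TTCCCGCC, TTTCCCGC, TTCGCGCC, TTGGCGCC and TTCCCGCG, the CHR was TTTGAA or TTCGAA, the GC-box CCGCCC, and the T-tract TTTTTTTT, on either strand. Intervals are 95% exact intervals and cover counting error only. With 2 replicates no test between samples exists, and p-values describe peaks, genes or windows of this peak set.

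The lists, motifs, tests and the rule for named genes were fixed before the data were examined. That rule takes lin-13 and unc-119, the genes of the 10 strongest promoter peaks, up to 4 members of each list with the strongest peaks, up to 2 alphabetically first members without a peak where fewer than 50% have one, the 3 strongest distal peaks, and any member of the DREAM, other synMuv B and P granule lists. The genes rpl-12, mys-1, lin-8, lin-15A and lin-56 were named outside the rule after their values were seen. List members that did not match a protein-coding gene name were egr-1, gnn-1, sur-8, lin-4, let-7, opt-2 and elt-5, and were left out. Several genes can share a name in the annotation (205 genes), and each was then counted.

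Alternatives fixed beforehand were the stronger part of the peak set, each replicate alone with the same number of top calls, the top pooled calls, windows of 250 and 1000 bp, the 5'-most end of each gene, the nearest 5' end only, a background of genes with any pooled call, smaller sequence windows, 5' ends without a peak as control, other overlap rules and the ce10 lists. Chosen after seeing the data were rotation of the peak flags along the gene order of each chromosome (10000 rotations), leaving out peaks within 250 bp of tRNA, snoRNA or snRNA genes, leaving out the surroundings of lin-13, and summits near 5' ends against shifted 5' ends without a peak.

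The tests were checked on simulated data. With no effect, 0 of 520 list tests over 19973 genes and 0 of 2080 6-mers over 2333 windows were called. With 35% of genes given a peak against 8.6% elsewhere, 5 lists of 59 to 173 genes were called in 100 of 100 cases, and 2 of 380 other lists were called. Power for smaller lists, for smaller excesses and for deficits was not simulated. Under clustered peak flags without effect, 0 of 130 rotation tests were called. No effect was planted for the rotation, and a test unable to call any list would also give 0 calls. The check therefore cannot decide how often the rotation calls a list wrongly. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.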

Results

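Chromatin immunoprecipitation with sequencing (ChIP-seq) was carried out on whole Caenorhabditis elegans at the first larval stage (L1), in a strain that carries an integrated transgene of lin-13 fused to EGFP, TY1 and FLAG tags. LIN-13 is a zinc finger protein of the synthetic multivulva (synMuv) class B, a group of genes that act together to keep vulval and germline programs off in somatic cells. The strain lacks functional unc-119 and is rescued by a copy of unc-119 on the same transgene. The labels name 1 group with 2 biological replicates, animals of both sexes, and a fragment size range of 150 to 350 bp. The labels name no second condition, so the design asks where the tagged protein was recovered on the genome and how well the 2 replicates agree, and no test between groups of samples was possible. Positions are given in the ce11 build, which has the chromosome lengths of the reference used here.

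The reproducible set held 2333 peaks, with a median signal of 79.4 and a range from 48.2 to 871. Signal is the authors' score per peak and its scale is not given in the sources used here. Each replicate contributed a list of 30000 calls that includes background, as did the pooled reads, and the sequencing depth of the libraries is not known. In replicate 1, 2475 calls had a q-value under 0.05, and in replicate 2, 5192 calls did. All 2333 reproducible peaks had a q-value under 0.05 in the pooled list and were its calls of highest signal.

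Many of the strongest calls were shared by both replicates. A call with its summit within 100 bp was found in both replicates for 2185 of the 2333 peaks (93.7%). Across these peaks the signal of the replicates had a Spearman correlation of 0.684 and a Pearson correlation of 0.723 on the log2 scale, which describes peaks and not independent samples. The reproducible set was derived from the lists of both replicates and equals the pooled calls of highest signal. The pooled signal draws on both replicates, so these values are not independent of that choice. The overlap of the top calls of each replicate list does not use it. The first peak of the pooled set, 48 bp upstream of tasp-1, ranked second in replicate 1 with a signal of 404.6 and first in replicate 2 with 475. Of the 500 strongest calls of replicate 1, 77.6% had a partner among the 500 strongest of replicate 2, against 0.1% for randomly placed calls. The share was 66.4% for the top 2333 calls, against 0.442% at random, and 26.4% for all 30000, against 5.85%.

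**Figure D1:**
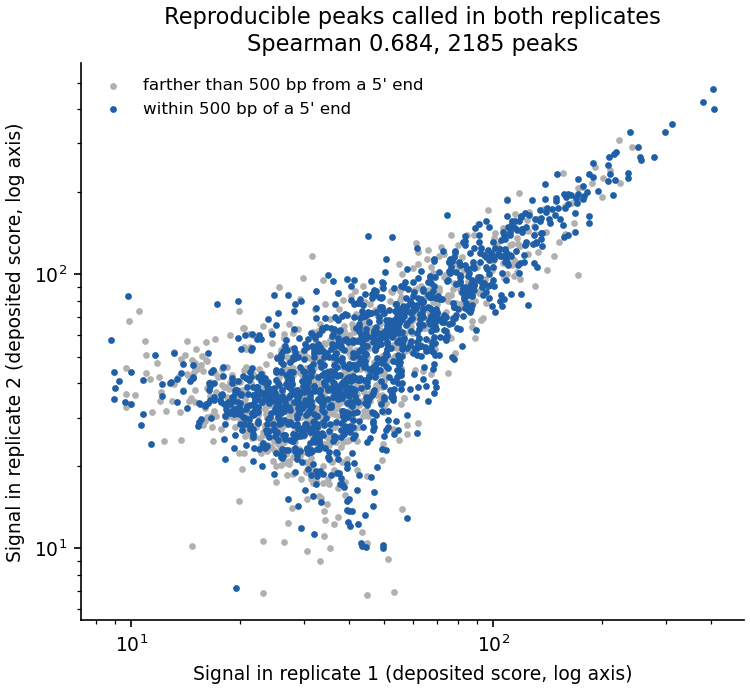
Signal of the 2185 reproducible peaks called in both replicates, replicate 1 on the x axis and replicate 2 on the y axis (deposited scores, log axes), with peaks within 500 bp of a protein-coding 5' end in blue and the others in grey. The strongest peaks lie close to a line and weaker peaks scatter more widely, with a Spearman correlation of 0.684.

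Peaks lay mostly just upstream of protein-coding genes. Of the 2333 summits, 1346 were within 500 bp of an annotated 5' end, 57.7% (95% exact binomial interval 55.7 to 59.7), against 22.9% ± 0.868 (SD over 1000 placements) for summits placed at random on the same chromosome. This is a 2.52-fold excess (one-sided permutation test, p = 0.001, the smallest that 1000 placements can give). Of these, 1224 (90.9%) were upstream of the nearest 5' end, and the median position was -161 bp (quartiles -256 and -71 bp). Summits avoided exons, which held 5.83% of summits against 29.8% ± 0.855 of random positions, while 73.3% lay between genes against 36.1% ± 0.874 (SD over 200 placements for both). In all, 1721 of 19973 protein-coding genes (8.62%) had a peak within 500 bp of a 5' end, and 408 summits served 2 or more genes, so that a peak at a shared promoter could not be assigned to either gene. A further 693 summits (29.7%) were farther than 1000 bp from any 5' end.

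Among genes with the strongest promoter peaks were 4 of the large ribosomal subunit and others with housekeeping roles. The tasp-1 peak (III, 10759133 to 10759397) had the highest signal, 871, and belongs to a gene named for the protease taspase. The second, with 806, was 177 bp upstream of cdc-48.1 (II, 10563454 to 10563689), which encodes an AAA ATPase that extracts ubiquitinated proteins. Signals of 802 at rpl-3 (III, 3867458 to 3867686), 663 at rpl-35 (III, 7854596 to 7854802) and 624 at rpl-15 (IV, 654809 to 655022) followed, the last of which is shared with the divergent gene K11H12.8. Next came iff-2, a translation elongation factor of the eIF5A family, with 562 (II, 8561325 to 8561519), the interval shared by syf-2 and K04G7.1 with 546 (III, 7162396 to 7162620), and that shared by rpl-20 and Y17G9B.5 with 545.5 (IV, 4749973 to 4750179). The last of the 10 were cox-5A, a subunit of cytochrome c oxidase, with 516 (III, 12905103 to 12905290), and puf-9, a Pumilio-family RNA-binding protein, with 513 (X, 5841219 to 5841411). These 10 summits all lay between genes, and each ranked among the top 15 calls of both replicates.

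The 3 strongest peaks farther than 1000 bp from any protein-coding 5' end were on X at 16929673 to 16929836 with a signal of 453.7, on X at 9465781 to 9465952 with 426, and on IV at 2602065 to 2602245 with 399. The first pair lay between genes, 5828 and 2523 bp from the nearest protein-coding 5' end, and the third lay in an intron of epg-9, 1015 bp from one. Each was called in both replicates, with signals of 210 and 239.8, 200.7 and 224, and 187 and 215.

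At lin-13 itself (III, 7700338 to 7709491, minus strand) no reproducible summit was within 500 bp of a 5' end, and the gene body held none. The ninth strongest peak of the whole set, with a signal of 528, had its summit 771 bp upstream of the gene, at position 7710262 (interval 7710162 to 7710332). Signals there were 240.7 in replicate 1 and 290.7 in replicate 2. The 20 kb upstream of lin-13 held 7 reproducible peaks and 21 pooled calls, more calls than in 99.8% of 10000 random windows of that width (median 6), and the 20 kb downstream held no pooled call. The rescue gene unc-119 (III, 10902641 to 10908935) had 1 reproducible peak, inside the gene at 10905085 to 10905408 with a signal of 49.97, and none near its 5' end.

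**Figure D2:**
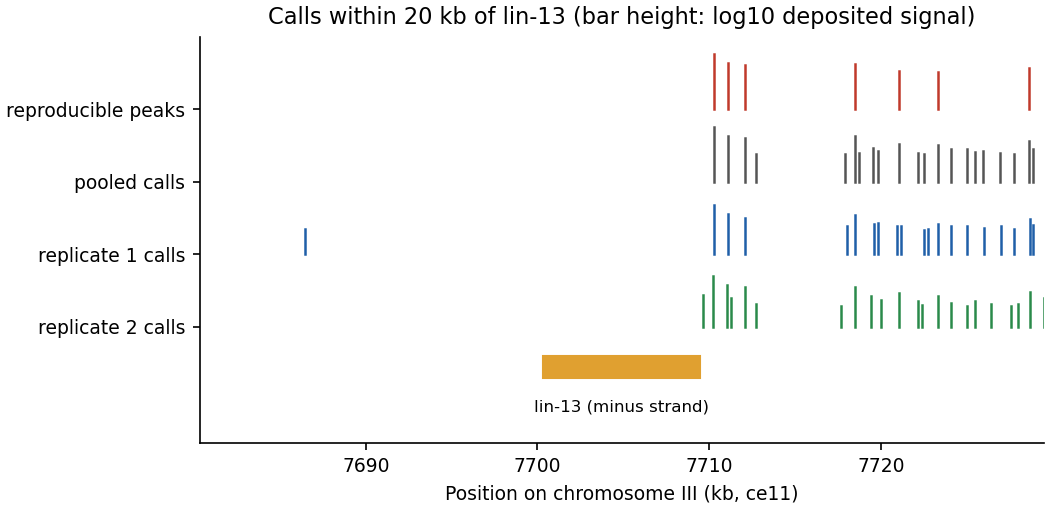
Calls within 20 kb of lin-13 on chromosome III (x axis, kb, ce11), one row for each of the reproducible, pooled, replicate 1 and replicate 2 lists, with each bar at a summit and its height the log10 of the deposited signal within that list. The orange box is the lin-13 gene, and the 7 reproducible peaks all lie to its right, upstream of the 5' end.

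Genes of the DREAM complex, the cell cycle, the ribosome, the spliceosome and the proteasome carried peaks more often than other genes. Of 26 gene lists fixed before the data were examined, 8 held more genes with a peak than the rest of the genome, 4 held fewer and 14 did not pass the threshold (two-sided Fisher exact tests, Benjamini-Hochberg adjusted over the 26 lists). The counts treat genes as independent units, although neighbouring genes can share a peak. Among genes with any pooled call, the odds ratio was nearer to 1 for most called lists, at 24.9 for the DREAM complex, 5.39 for the cell cycle, 21.4 for ribosomal proteins, 2.21 for the mitochondrial list, 0.0587 for chemoreceptors and 0.261 for C-type lectin and F-box genes, but it was 17.8 for synMuv A and C and 0.4215 for nuclear hormone receptors.

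The DREAM complex, a repressor of cell cycle genes that holds the synMuv B proteins LIN-35, LIN-9 and LIN-54, had a peak at 7 of its 8 genes (odds ratio 74.5, 95% interval 9.56 to 3359, adjusted exact p = 9.58e-07). Its strongest peaks were at lin-54 (signal 459), lin-9 (342), efl-1, an E2F factor (210), and lin-53, a histone chaperone (203). The lin-54 peak also lies 27 bp upstream of the divergent gene rpl-12. Signals at lin-35, the Rb homolog, dpl-1 and lin-52 were 187, 58.9 and 51.7, and lin-37 had no peak. When each summit was given only to its nearest 5' end, the odds ratio was 23.7 (adjusted exact p = 0.0002175).

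The synMuv A and C list, which includes the TIP60 acetyltransferase subunits, had peaks at 5 of 8 genes (odds ratio 17.7, 3.44 to 114, adjusted exact p = 0.000612). These were hat-1 (262), epc-1 (207), lin-38 (99.7), trr-1 (68.9) and mys-1 (65.4), with none at lin-8, lin-15A and lin-56. Without replicate 1 the odds ratio was 10.9 (adjusted exact p = 0.00695). Classes A and C were tested together, so these odds ratios cannot be read as an excess in either class alone. The list of other synMuv B and chromatin genes includes the methyltransferase met-2 and the HP1 homologs hpl-1 and hpl-2. It also holds lin-13 itself, counted as without a peak because its closest reproducible summit lay 771 bp upstream. Only 2 of the 13 genes had a peak, lin-36 (151) and set-2 (68.9), and the list did not pass (odds ratio 1.93, 0.208 to 8.85, adjusted exact p = 0.424). Of the 13, 8 had any call of the unthresholded pooled list, including arle-14 and hpl-1, and without replicate 2 the odds ratio was 0.916 (adjusted exact p = 1). The NuRD and MEC complexes, nucleosome remodelling assemblies, had 2 of 8 (mep-1 with 128, and lin-53; adjusted exact p = 0.29), with neither chd-3 nor dcp-66, and passed the threshold only for the top calls of replicate 1 (adjusted exact p = 0.0472).

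Cell cycle and DNA replication genes had a peak at 27 of 59 (odds ratio 9.07, 5.22 to 15.7, adjusted exact p = 3.05e-13). The strongest were cdc-48.1 (806), the sliding clamp gene pcn-1 (217.5), and the cyclin gene cyb-1 and the origin recognition gene orc-5, which share a peak of signal 144.7. The Aurora kinase genes air-1 and air-2 had none.

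Ribosomal protein genes had the highest count, 64 of 79 (odds ratio 46.9, 26.4 to 88.9, adjusted exact p = 9.55e-53). With a window of 250 bp in place of 500 bp the odds ratio fell to 3.63 (adjusted exact p = 0.000403). Their peaks were also stronger than those of other promoters. The 61 ribosomal protein peaks had a median percentile of 18.6 (0 is the strongest promoter peak) against 51.5 for the other 1285 (two-sided permutation test, adjusted p = 7e-05 over 7 lists, the smallest that 100000 resamples can give after adjustment). None of the other 6 lists with at least 10 genes with a peak differed in strength past the threshold (adjusted p from 0.139 to 0.788).

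Other housekeeping lists also stood above the background. Genes of the spliceosome and mRNA processing had a peak at 21 of 47 (odds ratio 8.66, 4.621 to 16.04, adjusted exact p = 2.83e-10), led by snr-4 (239.5), cpsf-1 (191.5), pabp-2 (190) and rsp-2 (189), while cpsf-2 and cpsf-4 had none. The odds ratio was 3.98 at 250 bp (adjusted exact p = 0.00262) and 5.01 among genes with any pooled call. Proteasome genes had 17 of 33 (11.4, 5.39 to 24.1, adjusted exact p = 9.77e-10), with rpn-3 (251), pbs-1 (171), rpn-9 (151.5) and rpt-2 (143) strongest, and the odds ratio was 4.67 among genes with any pooled call. For the mitochondrial ribosome and complex I, 18 of 72 genes had a peak (3.562, 1.961 to 6.186, adjusted exact p = 9.24e-05), with mrpl-28 (301), mrps-7 (264), mrpl-55 (179.7) and mrpl-49 (143) strongest and mrpl-10 and mrpl-11 without one. The small RNA pathway had 10 of 42 (3.33, 1.46 to 6.95, adjusted exact p = 0.00649), with mut-15 (183), rde-4 (145), nrde-4 (103) and rde-10 (102) strongest and alg-1 and csr-1 without a peak. That call was lost with a window of 250 bp (adjusted exact p = 0.188), with the nearest 5' end only (0.132) and with the 1166 peaks of highest signal (0.121).

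Chemoreceptor, nuclear hormone receptor, collagen, and C-type lectin and F-box genes carried peaks less often than other genes. Chemoreceptors, G protein-coupled receptors of sensory neurons, had peaks at 4 of 1302 genes (odds ratio 0.0304, 0.00827 to 0.0783, adjusted exact p = 4.69e-45). These were sri-5 (182), srh-16 (117), srh-2 (67.8) and srh-269 (62.0), and sra-1 and sra-10 had none. The srh-2 peak had no call within 100 bp in replicate 1. C-type lectin and F-box genes had 7 of 562 (0.130, 0.0520 to 0.271, adjusted exact p = 2.93e-13), led by fbxb-85 (234) and clec-126 (137), while clec-1 and clec-10 had none. Without replicate 2 the odds ratio was 0.234 (adjusted exact p = 2.30e-09). Cuticle collagen genes had 5 of 173 (0.3137, 0.1004 to 0.7481, adjusted exact p = 0.00928), with col-38 (174), col-71 (138) and col-2 (111) strongest and bli-1 and bli-2 without one. The collagen call was lost among genes with any pooled call (adjusted exact p = 0.516) and with the 1166 peaks of highest signal (0.498). Nuclear hormone receptor genes had 12 of 269 (0.492, 0.250 to 0.876, adjusted exact p = 0.0250), led by nhr-47 (177) and nhr-49 (142), while nhr-1 and nhr-10 had none. This call was lost without replicate 1 (adjusted exact p = 0.168), at 1000 bp (0.140), with the nearest 5' end only (0.230), and in a permutation that rotated the peak flags along the gene order (0.342).

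Lists for germline and developmental genes did not differ from other genes past the threshold. P granule and germ cell fate genes had 2 of 38 with a peak (mes-2 with 104.3 and nos-3 with 97.5; adjusted exact p = 0.833), and the P granule genes pgl-1 and glh-1 had none. Meiotic chromosome genes had 2 of 30 (him-17 with 58.9 and rad-51 with 52.3; adjusted exact p = 1), with chk-2 and coh-3 without a peak, and the odds ratio of 0.757 was 0.379 without replicate 2 and 0.374 without replicate 1, each with 1 of 30. Histone genes had 7 of 72 (adjusted exact p = 0.762), with the strongest at his-37 (347) and none at his-1. Heterochronic genes, which time larval development, had 2 of 9 (lin-66 with 131 and lin-28 with 95.6; adjusted exact p = 0.290), and daf-12 and hbl-1 had none. The lin-28 peak had no call within 100 bp in either replicate list. Without replicate 1, 3 of 9 heterochronic genes (odds ratio 5.44, from 3.03) and 3 of 38 P granule genes (0.931, from 0.589) had a peak. The vulval EGF and Ras genes had 3 of 21, lin-7 (168), sur-2 (64.8) and lin-45 (55.1), with an adjusted exact p of 0.520 and an odds ratio of 1.77, which was 1.16 without replicate 2. Notch and Wnt signalling (0 of 28, adjusted exact p = 0.290), Hox (0 of 6, adjusted exact p = 1) and hypodermis and seam genes (0 of 24, adjusted exact p = 0.378) had none, including apr-1, apx-1, ceh-13, egl-5, aff-1 and bed-3, with upper bounds of the odds ratio of 1.49, 9.01 and 1.76. Without replicate 1, 3 of 28 Notch and Wnt genes (upper bound 4.28) and 1 of 24 hypodermis and seam genes (upper bound 2.91) had a peak.

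Lists of markers of differentiated tissues did not pass, with shares on either side of that of all genes. Muscle genes had 5 of 42 with a peak (adjusted exact p = 0.520), including act-2 (131), unc-45 (97.2) and unc-60 (65.3), but not act-1 or act-3. Neuronal genes had 7 of 66 (adjusted exact p = 0.602), including unc-76 (95.9), egl-21 (80.4) and snb-1 (65.7), and the acetylcholinesterase genes ace-1 and ace-2 had none. The egl-21 peak had no call within 100 bp in replicate 1. Without replicate 2, the odds ratio of the neuronal list went from 1.26 to 0.522 with 3 of 66 genes, and that of the muscle list from 1.43 to 0.845, and without replicate 1 they were 0.8899 and 2.18. Intestinal genes had 1 of 39, hlh-11 (144), with an adjusted exact p of 0.378, and homeobox genes of the ceh series had 2 of 63, ceh-38 (270) and ceh-39 (57.5), with an adjusted exact p of 0.290 and an odds ratio of 0.347, which was 0.549 without replicate 2.

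**Figure D3:**
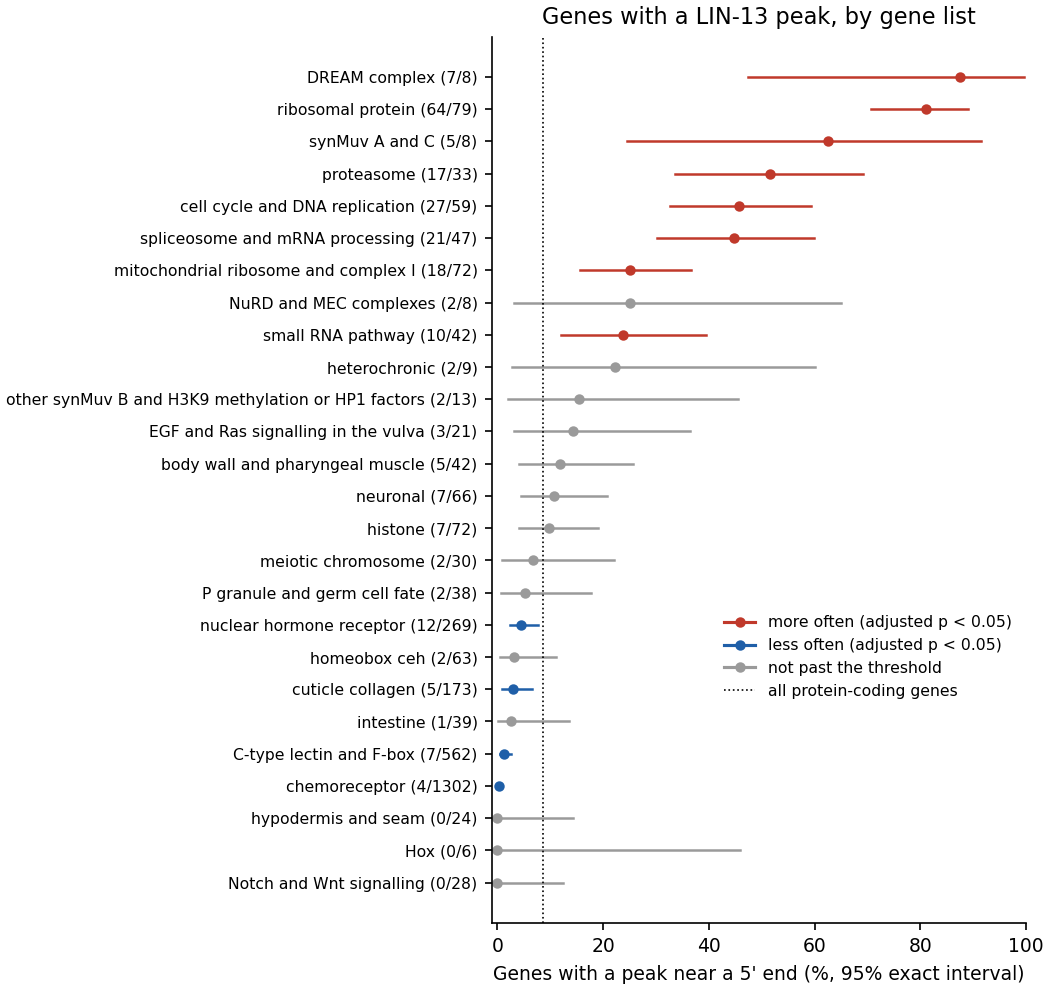
Percent of the genes of each of 26 lists that have a reproducible peak within 500 bp of a 5' end (x axis), with 95% exact binomial intervals as lines and the count of genes beside each name. Red lists held more genes with a peak than other genes, blue lists fewer, grey lists did not pass, and the dotted line marks the 8.62% of all protein-coding genes.

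Peaks were unevenly spread over the chromosomes. Chromosome III had 34.6 peaks per Mb, I had 28.9, II 25.33, IV 21.3, X 19.1 and V 15.4. The share of protein-coding genes with a peak ranged from 13.7% on III and 12.7% on I to 5.55% on V and 5.35% on X. Per base, X held fewer peaks than the autosomes (ratio 0.792, 95% interval 0.704 to 0.889, exact binomial p = 5.19e-05), but relative to annotated 5' ends the ratio was 1.04 (0.925 to 1.17, exact binomial p = 0.493). Without replicate 1 that second ratio was 1.12 (exact binomial p = 0.0491). Both ratios count all summits, distal ones included, and X had the lowest share of genes with a peak near a 5' end, 5.35%. The second ratio therefore does not mean that promoters on X carried peaks as often as those on autosomes. When each chromosome was divided into 3 equal parts, the middle part held 1.31 times the density of the outer parts (1.21 to 1.43, exact binomial p = 1.80e-10), and 1.04 times relative to 5' ends (0.959 to 1.14, exact binomial p = 0.318). On the autosomes the ratio per base was 1.41 (1.29 to 1.54) and on X it was 0.849 (0.666 to 1.08).

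Summits held GA repeats, GC-rich words and E2F-like sites more often than their flanks. Within 100 bp of the summit a GA repeat of the form GAGAGAG was found at 21.3% of peaks, against 3.60% of windows 1000 bp away on one side (exact McNemar test, adjusted exact p = 2.24e-78 over 9 motifs). A GC-box, the core of sites of SP1-like factors, was at 9.39% against 3.34% (adjusted exact p = 1.35e-17), an E2F-like site at 6.77% against 2.62% (6.45e-11), and an E-box palindrome at 17.6% against 12.3% (1.19e-06). The cell cycle homology region (CHR), which LIN-54 binds in textbook accounts, was less frequent, 45.18% against 51.01% (adjusted exact p = 0.000126). So were the T-tract (14.3% against 19.5%, 2.76e-06), the GATA site (29.83% against 35.96%, 1.10e-05) and a TATA-like word (13.2% against 18.3%, 3.19e-06). At summits near 5' ends the CHR was at 51.71%, close to the share of flanks. Shifted 5' ends without a peak had it at 56.32% (adjusted Fisher exact p = 0.00119). The less frequent words consist mostly of A and T, and GC content was higher at summits, so base composition was not separated from these deficits. Nearly every window held a CpG dinucleotide, 99.9% against 99.4% (adjusted exact p = 0.00754). That small difference did not pass without replicate 1 (adjusted exact p = 0.109) or for all summits against 5' ends without a peak (0.0593). For summits near 5' ends against shifted 5' ends without a peak it passed, 99.93% against 99.07% (adjusted Fisher exact p = 0.000138).

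**Figure D4:**
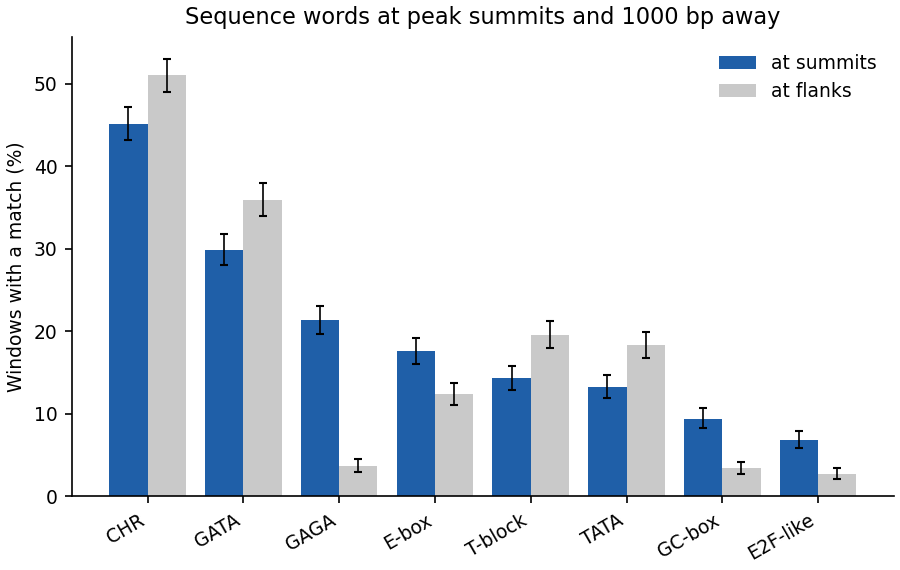
Percent of windows with at least 1 match to each word (y axis) within 100 bp of the 2333 summits (blue) and of positions 1000 bp away (grey), with 95% exact binomial intervals as error bars. GA repeats, GC-boxes, E2F-like sites and E-boxes are higher at summits, and CHR, GATA, T-tract and TATA-like words are lower.

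Among all 2080 6-mers, 625 were more frequent at summits and 634 less frequent (exact McNemar tests, Benjamini-Hochberg adjusted). The most enriched were GAGAGA, at 40.6% of summits against 12.3% of flanks, CGTCTC at 27.8% against 6.13%, and ACGCAG at 24.9% against 4.67%. Of the 625 enriched 6-mers 327 held a CpG, against 52 of the 634 depleted ones and 604 of all 2080. Summit windows held 10.9 ± 4.26 CpG (SD over windows) and flanks 7.19 ± 3.71, and GC content was 42.9% ± 6.93 and 36.9% ± 7.33, so base composition itself differed between both kinds of window. Annotated 5' ends without a peak held 6.57 ± 3.19 CpG.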

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

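Calls of the pooled list that did not reach the reproducible set also lay near 5' ends more often than random positions, and this test was chosen after the lists had been seen. Of the 27667 such calls, which the main peak set leaves out, 7561 (27.3%, 95% exact interval 26.8 to 27.9) had a summit within 500 bp of a protein-coding 5' end. Random placement gave 22.9% ± 0.249 (SD over 1000 placements; one-sided permutation p = 0.001, the smallest possible). The excess was 1.19-fold, against 2.52-fold for the reproducible peaks. It stands out as a signal in calls outside the main comparison. The control alignment was not analysed here, and no explanation was tested.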

How the results depend on the processing

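Alternatives chosen after the data were seen were the rotation, the removal of peaks at small RNA genes or around lin-13, and the shifted 5' ends. The top pooled calls are the same set as the reproducible peaks, so that alternative tests nothing and is not counted. Of the recomputed values of the main results, 75 kept their side of the threshold or moved by less than their error, 3 moved and 1 newly passed, and none past the threshold was reversed. Some lists that did not pass changed direction, as the neuronal list did without replicate 2 (odds ratio 0.522). Without either replicate in turn, the density of X against autosomes relative to 5' ends ranged from 1.02 to 1.12, and the latter, without replicate 1, passed the threshold (exact binomial p = 0.0491). Counting any overlap raised the share of peaks called in both replicates to 99.3%, and requiring a reciprocal overlap of 50% lowered the Spearman correlation to 0.631. With a window of 1000 bp, 1 list, nuclear hormone receptors, had weaker peaks than other promoters (permutation test, adjusted p = 0.0162), against 0 lists at 500 bp. The cause of these changes was not tested. Among the other recomputed values, 469 kept their side or moved by less than their error, 64 moved, 11 lost the threshold and 2 gained it. Of 83 named genes with a peak, 76 had one among the top calls of replicate 1, 81 among those of replicate 2, 49 with a window of 250 bp and 68 with the nearest 5' end only. Read depth is unknown and its effect on the number of weak peaks could not be assessed. No paired analysis was possible because there is 1 group only.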

Other observations

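Classes of noncoding RNA genes, the word combining the enriched 6-mers, the tests of the lin-13 cluster, of isolated transfer RNA genes, of strongly transcribed genes and of GC content at distal summits were examined only after the results were seen, and for the lin-13 and isolated transfer RNA tests the explanation or the criterion was also changed after the value was known. Peaks were concentrated at several classes of small RNA genes. Of 612 tRNA genes, 125 (20.4%) had a summit within 250 bp of their 5' end, and 114 summits were near one, against 6.44 ± 2.51 at random (SD over 1000 placements, two-sided permutation test, adjusted p = 0.0032 over 8 classes). The snoRNA genes, which guide RNA modification, drew 64 summits against 4.08 ± 2.02, and the snRNA genes of the spliceosome 21 against 1.45 ± 1.18 (permutation tests, both adjusted p = 0.0032). Genes of piRNAs, germline small RNAs, had fewer summits than random, 28 against 77.5 ± 8.13 (permutation test, adjusted p = 0.0032), and microRNA genes had 6 against 2.75 ± 1.64 (permutation test, adjusted p = 0.14). Genes of the ncRNA class drew 352 against 72.3 ± 8.56 (permutation test, adjusted p = 0.0032), lincRNA genes 7 against 2.271 ± 1.496 (0.00799), and pseudogenes 15 against 22.2 ± 4.56 (0.14). Random placement does not account for nearby protein-coding promoters, and the summits farther than 500 bp from a coding 5' end were 93 of 114 for tRNA, 41 of 64 for snoRNA, 18 of 21 for snRNA, 206 of 352 for ncRNA and 4 of 7 for lincRNA genes.

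The enriched 6-mers overlap in a longer word, GAGACGCAG, which lay within 100 bp of 325 of the 2333 summits (13.9%) and of 1.11% of flanks. It was at 17.5% of distal summits and at 12.04% of summits near 5' ends (two-sided Fisher exact p = 0.000918), and at 1.78% of shifted 5' ends without a peak. Of its 357 matches, 62.5% were within 40 bp of the summit. GA repeats were likewise more frequent at distal summits, 31.3% against 14.5% (Fisher exact p = 1.80e-18). Comparisons of motif and list were not among the tests fixed beforehand, and covered only the E2F-like, CHR, GA repeat, T-tract and GC-box words. Among these 35 comparisons, the CHR was at all 20 promoter peaks of spliceosome and mRNA processing genes, against 50.98% of other promoter peaks (adjusted Fisher exact p = 7.15e-05). An E2F-like site was at 7 of 26 cell cycle peaks (26.9%) against 7.35% (adjusted Fisher exact p = 0.0453). The other 33 comparisons did not pass.

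The cluster of calls beside lin-13 ran over 28094 bp upstream of the gene (III, 7710262 to 7738356), with 31 pooled calls and 8 reproducible peaks, and ended sharply on both sides. Because the strain carries a lin-13 transgene, extra copies of its DNA are a candidate explanation. Equal extra copies of the gene and both its flanks would raise calls in the gene body as in the 20 kb upstream, whose 21 calls predict 7.17 there after lowering the density for genes (one-sided exact binomial p = 0.00209), but the body held 0 and windows of its length upstream held at least 6. The 20 kb downstream also held 0 (median of random windows 6), so the counts are not those that this form would give. The form was set after the counts were known, however, so this is not an independent test of it. A gene body without a call is also not rare, as random windows of its length held a median of 2. Calls were made against a control alignment and they cluster, while the binomial test takes them as independent. Copies that raise calls unequally stay open, since the lists hold no coverage, and no biological explanation was tested.

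Peaks at tRNA genes could come from reads shared between near-identical copies. Genes of a sequence found once had a peak at 14.7% (21 of 143, 95% exact interval 9.33 to 21.6), and those of a repeated sequence at 22.2% (two-sided Fisher exact p = 0.0579). Of the isolated genes whose every 30-mer is unique in the genome, 1 of 18 (5.56%, 0.141 to 27.3) had a peak, against 1.18% at random, and these are too few to decide. Preferential recovery of strongly transcribed genes was weighed by the collagen, muscle and intestine lists, of which only 1, collagen, was depleted past the threshold. That call was lost among genes with any pooled call (adjusted Fisher exact p = 0.516). With 42 muscle and 39 intestine genes a depletion could not readily pass, so the criterion could not decide. The ribosomal protein list, with peaks at 64 of 79 genes, was not part of it. Preferential recovery too cannot be told apart from binding. No control list was analysed here that would settle either point.

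Stronger peaks held more CpG, with a Spearman correlation of 0.284 across all summits (p = 0.0001, the smallest that 10000 permutations can give), which are not independent replicates. The contrast of promoter and distal summits alone does not account for it, since the correlation was 0.315 (95% interval 0.266 to 0.362) within summits near 5' ends. Other properties of promoters were not tested. GC content was taken from the reference sequence around each summit, and that of the fragments was not measured. Across all summits the partial correlation given this GC content was 0.214 (0.175 to 0.253), so the sequence value did not remove the link there. That value pools summits near 5' ends with distal ones, and it cannot decide whether GC content of the fragments accounts for the link. Near 5' ends the partial correlation was 0.2245 (0.173 to 0.275). At distal summits the correlation was 0.156, and the partial one 0.0189 (-0.0557 to 0.0933), so that GC content could account for it there. Given GC content, the link was thus seen near 5' ends and not at distal summits. A link of CpG-rich promoters to stronger LIN-13 recovery is a hypothesis, and shared chromatin accessibility was not tested.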
